A study of Mus musculus with 9 samples.

How the data were processed

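Liver miRNA was measured in male C57BL/6J mice, an inbred laboratory strain, at 20 weeks of age on 9 one-colour Agilent mouse miRNA arrays, 3 in each of 3 groups. Per the labels' protocols, the control group ate chow for 17 weeks from 3 weeks of age, and the other groups ate a diet with 45% of its energy from fat over the same time. From 15 weeks of age, after 12 weeks on that diet, the high fat diet group received saline by stomach tube for 5 weeks and the metformin group received metformin at 3 mg per kg per day, a dose given as stated there that the data at hand cannot check. Whether control mice received a vehicle is not given in the sources used here. Each sample pooled the livers of 4 mice of its group. RNA came from 15 mg of tissue by Trizol and the mirVana kit and was labelled with Cy3. Because each array measured a pool, the spread between arrays is a spread between pools and not between single mice, and the p-values apply to pools.

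Per the file headers, the 9 scanner files hold spot intensity from Agilent Feature Extraction 11.5.1.1, with the signal of each spot after background subtraction and no scaling between arrays. Per the submitters' processing notes the version was 10.7; the difference was not resolved. The deposited value table is on the log2 scale. It was checked against the scanner files and held the log2 of the software's total signal per miRNA plus 1 constant per array, between -2.35 and -0.71, with 0 to 6 miRNAs per array departing by more than 0.001. How the authors chose those constants is not given in the sources used here. The arrays carried 1881 mouse miRNAs, read by 4415 probes on 56430 spots per array (58594 spots with controls). No spot was saturated, and 0 pairs of arrays were identical. The headers name an older mouse genome build than the gene table at hand and the files hold no probe sequences, so no genome coordinates are given. The miRNA names are those of the files without the species prefix mmu.

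In the design fixed before the data were examined, each probe's background-subtracted intensity was averaged over its spots without outlier marks. Values were divided by the array's 75th percentile over the 124 probes detected on all 9 arrays. A probe counted as detected where more than a share of 0.5 of its spots lay well above background. Scaled values were floored at the 1st percentile of the detected values (0.0272 of the scaling percentile) and put on the log2 scale. Each miRNA was represented by the probe with the highest mean over all arrays, and miRNAs detected on all 3 arrays of at least 1 group were tested. No level of 1 miRNA was set against that of another. The reading with all spots follows this design throughout.

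A second reading was chosen after seeing the data, because 6 of the 9 arrays had strips of columns at their left or right edge where spots of bright probes gave no signal. A probe was bright where the 80th percentile of its spots exceeded an intensity of 100, and a spot counted as without signal under 50% of that level. Working inward from each edge in steps of 4 columns, columns were left out while at least 10% of such spots lacked signal, up to the first pair of steps below that share. Each probe became the median of its remaining spots without non-uniformity marks. The 425 probes with under 3 such spots on any array were dropped, and the floor was 0.0406 of the percentile. In a test on simulated data, strips planted on the second high fat diet array and the third metformin array were found at their planted width (24 columns on the left and 28 on the right). The median absolute log2 error of bright probes was 0.0079 and 0.0093, against 0.467 and 0.460 with the mean of all spots. The planted strips had sharp edges and a uniform shift of 2 rows, unlike the strips found here, which set in gradually. Error was taken against the median over spots, the summary that this reading uses. The test therefore does not give the error on the real strips.

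Comparisons used limma 3.58.1 in R 4.3.3 (data read with version 1.17.8 of data.table) as a model of 3 group means with 1 shared estimate of the spread. The tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the miRNAs tested in a comparison, with 0.05 as the threshold. An exact permutation test of 3 against 3 arrays cannot go below p = 0.1. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.20 with all spots and 0.12 with the strips left out. In 20 simulated data sets with 20 changed miRNAs, limma recovered 10.8% of changes of 0.5 and 77.8% of changes of 1 on the log2 scale with all spots. Without the strips it recovered 66.8% and 97.0%. Of the calls in these simulations 3.12% to 6.52% were false. Noise there was drawn independently for each miRNA, while levels on the arrays were correlated between miRNAs. These shares may therefore not hold for the real data.

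Before the data were examined, 21 lists were written. They covered hepatocyte-enriched miRNAs, regulators of lipid and cholesterol, regulators of insulin and glucose, miRNAs reported raised in fatty livers, the let-7, miR-30, miR-29 and miR-17-92 families, p53-responsive miRNAs and the cluster of miR-183, miR-96 and miR-182. Others were marker lists for stellate and mesenchymal cells, leukocytes, erythroid cells, endothelium, biliary and other epithelium, muscle, pancreas and neural cells. The last were the imprinted Dlk1-Dio3 cluster, the Sfmbt2 cluster and the late miRBase entries, numbered from 5046 upward on the array. The 12 lists with at least 3 tested members were tested with camera in limma at a preset correlation of 0.01, adjusted over 36 tests of lists and contrasts per reading, and again with an estimated correlation. Camera compares a list with the other tested miRNAs.

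Named miRNAs follow a rule set before the data were examined. In each comparison these were up to 10 of the largest rises and up to 10 of the largest falls among miRNAs that passed with no overlap between the groups' arrays. Where fewer than 10 passed, the 10 with the smallest p were added as values. Up to 4 members with the smallest p were named for each list that passed, and 12 miRNAs were always named. The same rule was applied to the reading with strips left out. Members of the let-7, miR-30, miR-29, miR-199, miR-466 and miR-669 families differ by few bases, so their probes may not tell them apart. The text says where the probe tested was detected on under 2 of the 3 arrays of a group, since a size then rests on values near background.

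The alternatives fixed before the data were examined were normexp background correction (offset 50), quantile normalization, a percentile over all probes, the mean over a miRNA's probes, the software's total signal per miRNA, and the deposited value table. Others were a filter to miRNAs detected on all arrays, no filter, blocks for replicate number, slide and row of the slide, the trend and robust options of limma, a fit of only the pair of groups compared, and leaving out each array in turn. Normexp was run on median spot intensity because the files hold no mean intensity. The slide block is the same as leaving out the third control array, the single array of its slide, and the row block, fitted to the 8 arrays of the other slide, leaves it out too. There the high fat diet arrays share the first row and the control arrays the second, so the row is estimated from the metformin arrays alone. Added after seeing the data were the reading with strips left out and, within it, quantile normalization, the replicate block, the row block, the trend and robust options and leaving out each array. Opposite changes with diet and metformin were set against 1000 simulated data sets of unchanged groups that share the high fat diet arrays, given as median with the central 95%. As many of the most changed miRNAs of each such data set were followed as had passed with the diet.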

Results

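The data are miRNA levels in the livers of 9 pools of male C57BL/6J mice, 3 pools in each of the control, high fat diet and metformin groups. Metformin, a drug that lowers blood glucose in type 2 diabetes, was given on top of the high fat diet. Of 1881 mouse miRNAs on the array, 1668 were detected on no array by the scanner software. Between 136 and 190 miRNAs were detected per array. The 75th percentile of intensity used for scaling lay between 188 and 265 in the control arrays, 215 and 450 in the high fat diet arrays, and 274 and 354 in the metformin arrays, over a mean local background between 16.1 and 20.9. After scaling, 139 miRNAs could be tested with all spots. In order of replicate number, 105, 115 and 134 of these were detected on the control arrays. On the high fat diet arrays 97, 130 and 138 were detected, and on the metformin arrays 139, 138 and 138. Nearly all tested miRNAs could thus enter through the metformin group, and fewer through either other group.

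The arrays differed in a technical respect that was not balanced between the groups. Strips at the left or right edge, in which spots of bright probes gave no signal, were present on 3 of 3 control arrays, 2 of 3 high fat diet arrays and 1 of 3 metformin arrays. Each comparison is therefore given with all spots, the design fixed beforehand, and with these strips left out (the strip-free reading). The latter was chosen after seeing the data, and 143 miRNAs could be tested in it. Leaving the strips out removed 43.8%, 43.5% and 41.1% of the miRNA spots on the control arrays, in order of replicate number. It removed 53.6%, 0% and 33.6% on the high fat diet arrays and 0%, 31.1% and 0% on the metformin arrays. The fit gave all arrays the same weight. Correlations between the arrays across miRNAs, which are not independent replicates, lay between 0.957 and 0.996 within groups with all spots and between 0.987 and 0.998 with the strips left out. Arrays of different groups correlated between 0.947 and 0.995 with all spots and between 0.977 and 0.995 with the strips left out, so these ranges overlapped. Levels are log2 values relative to each array's 75th percentile, with SD and n = 3 per group.

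**Figure D1:**
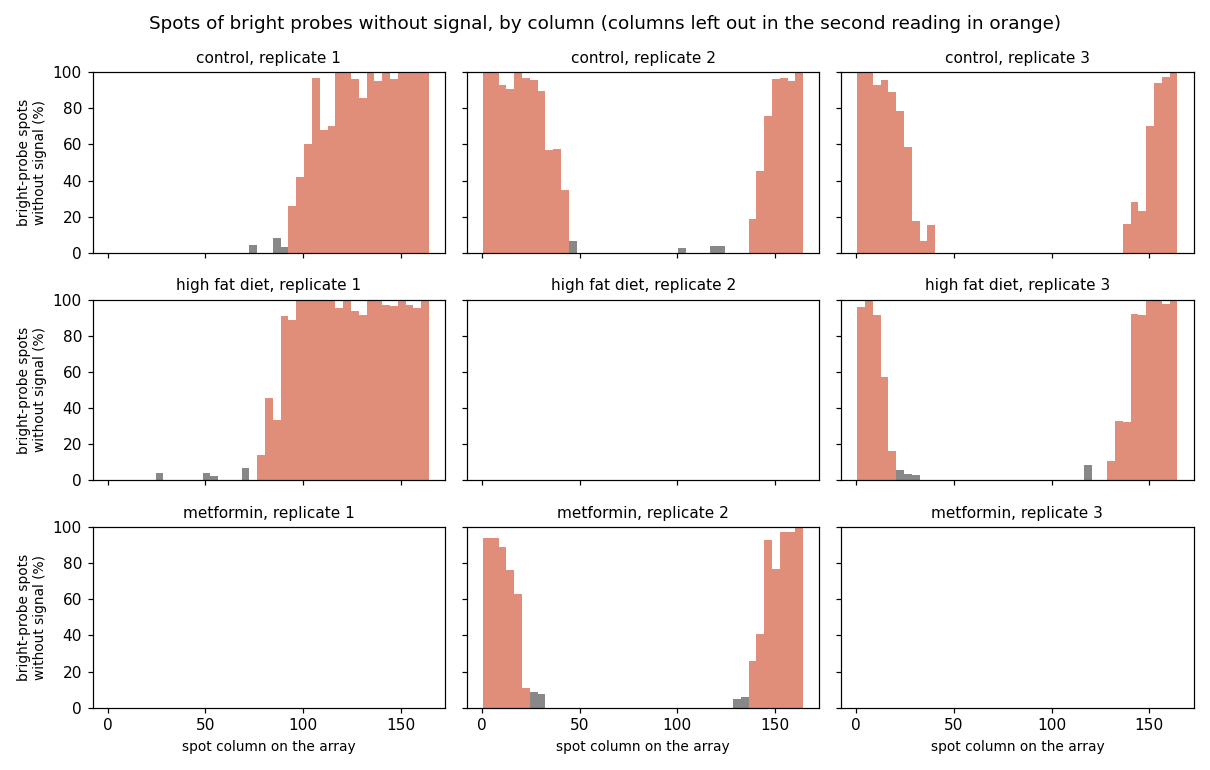
Percent of the spots of bright probes without signal (vertical axis) in each step of 4 columns across the array (horizontal axis, column number), 1 panel per array, with orange marking the columns left out. Strips lie at the edges of 6 arrays, where 23.6% to 50.1% of such spots on the array gave no signal, while the second high fat diet array and the first and the third metformin arrays show 0%.

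The high fat diet group was set against the control group to ask which liver miRNAs differed after 17 weeks of the diet. With the diet miR-34a-5p, a p53-responsive miRNA that represses Sirt1, rose 1.79-fold, from -2.19 ± 0.35 in control to -1.35 ± 0.19 (log2 difference 0.84, SE 0.20, adjusted p = 0.0464 by limma). In the strip-free reading it rose 2.58-fold, from -1.92 ± 0.09 to -0.55 ± 0.33 (1.37, SE 0.14, adjusted p = 0.000265). In both readings all 3 high fat diet arrays lay above all 3 control arrays. Among the falls, miR-3102-5p was 1.87-fold lower with all spots (-0.90, SE 0.16, adjusted p = 0.0288) and 1.51-fold lower with the strips left out (-0.60, adjusted p = 0.00665). The level of miR-202-3p fell 1.49-fold with all spots, from -3.38 ± 0.15 to -3.96 ± 0.12 (-0.58, SE 0.15, adjusted p = 0.0464), and 1.62-fold with the strips left out (-0.69, SE 0.11, adjusted p = 0.00458), where its other probe read -0.38.

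With all spots 9 of 139 miRNAs passed, 1 higher and 8 lower, and with the strips left out 20 of 143 passed, 6 higher and 14 lower. Of 137 miRNAs tested in both readings, 7 passed in both: miR-34a-5p, miR-3102-5p, miR-202-3p, miR-6538, miR-3963, miR-1904 and miR-149-3p. The falls of miR-6538 (-0.69 and -0.67), miR-3963 (-0.83 and -0.53) and miR-1904 (-0.78 and -0.59) are given with all spots first. miR-149-3p was also lower, but its size is not given, since with all spots it was detected on 1 of 3 control and 1 of 3 high fat diet arrays, and with the strips left out on 2 and 1. The remaining falls with all spots were those of miR-8110 (-0.79) and miR-7042-5p (-0.70). These did not pass with the strips left out, at -0.39 (adjusted p = 0.108) and -0.16 (adjusted p = 0.526). Without the strips miR-185-5p rose 1.45-fold (0.53, SE 0.10, adjusted p = 0.00827), and miR-342-3p (0.39), miR-425-5p (0.37), miR-199a-3p (0.31) and miR-1839-5p (0.39) also rose. With all spots these 5 did not pass, and miR-1839-5p was at -0.09, detected on 1 of 3 control arrays. Further falls in the strip-free reading were those of miR-211-3p (-0.59), miR-3077-5p (detected on 1 of 3 high fat diet arrays, so without a size), miR-8101 (-0.54), miR-677-3p (-0.49, not testable with all spots), miR-3960 (-0.47), miR-5126 (-0.47), miR-7082-5p (-0.46) and miR-3473g (-0.36). Where both probes of a called miRNA were detected on all arrays, they had the same sign for 4 of 4 with all spots and 12 of 12 with the strips left out. They differed over 1.5 times for miR-3102-5p, miR-6538 and miR-8110 with all spots (other probe -0.57, -1.13 and -0.39) and for miR-1904 and miR-202-3p with the strips left out (-0.27 and -0.38). The median difference over all tested miRNAs was -0.22 with all spots and 0.03 with the strips left out, so relative to that median miR-34a-5p stood further above 0 and the falls stood nearer to 0 with all spots.

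Complete separation of the groups' arrays was found for 32 miRNAs (23.0%) with all spots and 53 (37.1%) with the strips left out. Chance gives 10% on average. Levels were correlated between miRNAs, so shares well above 10% can arise by chance. The spread of the chance share was not worked out. With all spots the count of 9 was 3 without the first control array, 2 without the third high fat diet array, 1 without the second control array and 0 without any 1 of the other 6 arrays. Of the 3 miRNAs given first, miR-34a-5p passed only without the second control array, miR-3102-5p only without the first control or the third high fat diet array, and miR-202-3p in none of the 9 cases. In the strip-free reading these 3 passed without each array in turn. On the slide that held 8 of the arrays the high fat diet arrays lay in the first row and the control arrays in the second. With the row as a block, in fits of these 8 arrays that also leave out the third control array, limma called 0 miRNAs in either reading, with 13 and 31 at an unadjusted p under 0.05. Without that array and with no row block it called 0 with all spots (32 at an unadjusted p under 0.05) and 40 with the strips left out. In the fit with the row miR-34a-5p stood at 0.84 (adjusted p = 0.523, range over the alternatives 0.0132 to 0.946) with all spots. Without the strips it stood at 1.27, SE 0.29 (adjusted p = 0.0764, range 9.95e-06 to 0.0764). The count of 20 was 40 without the third control array, 8 without the first, and 6, 7 and 13 without the first high fat diet, second high fat diet and second metformin arrays. With the slide as a block, which leaves out the third control array, limma called 0 miRNAs with all spots (32 at an unadjusted p under 0.05). Deviations from the group mean were compared between control and high fat diet arrays of the same replicate number. They correlated at 0.514, 0.426 and 0.229 with all spots and at -0.00377, 0.371 and -0.223 with the strips left out. No pairing of pools is given in the sources used here. With the replicate numbers as a block 7 miRNAs passed with all spots. There miR-149-3p and miR-202-3p did not (adjusted p = 0.0508 each by limma, ranges 0.0476 to 0.961 and 0.0112 to 0.941).

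**Figure D2:**
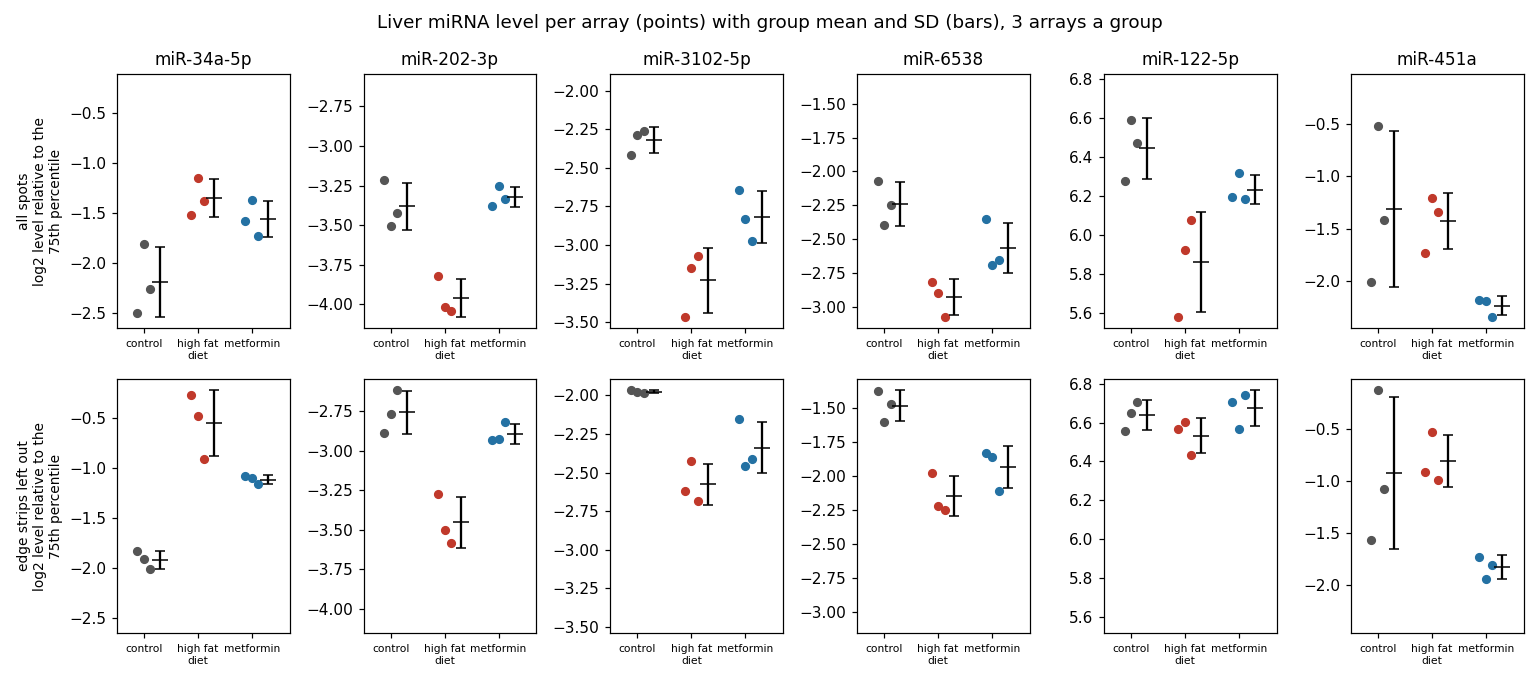
Log2 level relative to the array's 75th percentile (vertical axis) of 6 miRNAs in the control, high fat diet and metformin groups (horizontal axis), with all spots in the upper panels and the edge strips left out in the lower; points are arrays and bars the mean with SD (n = 3). With the strips left out miR-34a-5p averaged -1.92 in control, -0.55 with the high fat diet and -1.12 with metformin, and miR-202-3p averaged -2.76, -3.45 and -2.89.

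Among miRNA groups the late miRBase entries, whose functions are mostly uncharacterised, lay lower with the high fat diet relative to the other tested miRNAs. Of 782 on the array 19 were tested, and with all spots 0 rose and 3 fell (miR-8110, miR-6538 and miR-7042-5p), or 0 and 6 adjusted over the list alone. All 19 differences were negative (median -0.47, adjusted p = 0.00289 by camera). The call was lost at adjusted p = 0.510 with an estimated correlation, and without the first control array (median -0.23, adjusted p = 0.211, range over the alternatives 0.000132 to 0.211). With no filter, where 759 of the 782 were detected on no array, the list passed in the opposite direction (median 0, adjusted p = 0.0225). Without the strips 0 rose and 4 fell (miR-6538, miR-5126, miR-8101 and miR-7082-5p), or 0 and 5 adjusted over the list alone. In that reading 18 were negative (median -0.34, adjusted p = 4.46e-05; adjusted p = 0.739 with an estimated correlation).

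Markers of stellate and mesenchymal cells, the fibre-forming cells of the liver, passed the list test upward with all spots. Of 11 on the array 6 were tested, 0 passed singly or adjusted over the list alone, and 5 were positive (median 0.13, adjusted p = 0.0165). The call was lost at adjusted p = 0.516 with an estimated correlation. It was also lost with the slide as a block (adjusted p = 0.131) and with the row as a block (adjusted p = 0.390, range over the alternatives 0.00770 to 0.390), and without the third control array (adjusted p = 0.131) or the third high fat diet array (adjusted p = 0.141). Further losses came with quantile normalization (0.0635), the percentile over all probes (0.0595) and only miRNAs detected on all arrays (0.245). With no filter the list passed in the opposite direction (median 0, adjusted p = 0.0148). With normexp background correction the median turned to -0.18 (0.260), where that of all tested miRNAs was -0.33. Members included miR-199a-3p at 0.57. miR-199b-5p and miR-199a-5p were detected on 1 and 0 of 3 control arrays, so no size is given, and probes may not tell this family apart. In the strip-free reading 1 member, miR-199a-3p, rose, also adjusted over the list alone, and the list did not pass (median 0.23, adjusted p = 0.0753).

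Regulators of insulin and glucose, and of lipid and cholesterol, passed upward with the strips left out. Of 17 insulin and glucose regulators 11 were tested and 0 passed singly or adjusted over the list alone. All 11 were positive (median 0.22, adjusted p = 0.0274; adjusted p = 0.739 with an estimated correlation), with miR-152-3p at 0.33, miR-378a-3p at 0.24 and miR-497a-5p at 0.22. Of 22 lipid and cholesterol regulators 12 were tested. Of these 2 rose (miR-34a-5p and miR-185-5p) and 0 fell, or 3 and 0 adjusted over the list alone, and 11 were positive (median 0.17, adjusted p = 0.0467; adjusted p = 0.755 with an estimated correlation). With the row as a block neither passed (adjusted p = 0.209 and 0.0507, ranges over the alternatives 0.0129 to 0.269 and 0.0234 to 0.271), nor with quantile normalization (0.269 and 0.271). The first call ended without the first control array (adjusted p = 0.0571). The second ended without that array (0.0908), the second high fat diet array (0.115) and the first or second metformin array (0.0611 and 0.0514). With all spots the lists did not pass, with medians of 0.05 and -0.13.

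Several miRNAs with known roles in liver did not pass. miR-122-5p, the most abundant miRNA of hepatocytes, was at -0.58 (SE 0.17, adjusted p = 0.0682) with all spots and -0.10 (adjusted p = 0.422) with the strips left out. Its probes read -0.58 and 0.37 with all spots and -0.10 and -0.11 with the strips left out. miR-21a-5p, raised in many forms of tissue injury, was at -0.24 and 0.01. The insulin sensitivity regulators miR-103-3p and miR-107-3p were at -0.00 each with all spots and at 0.06 and 0.20 with the strips left out. miR-192-5p was at -0.24 and 0.08, let-7a-5p at -0.46 and 0.10, myeloid miR-223-3p at -0.26 and 0.09, and erythroid miR-451a at -0.11 and 0.11. miR-33-5p, from an intron of Srebf2, was detected on 0 arrays in either reading, miR-802-5p on 1 array with all spots and 2 with the strips left out, and miR-200b-3p on 0 and 2, so that they were not tested.

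The metformin group was set against the high fat diet group to ask which miRNAs the drug moved in mice on the same diet. Without the strips miR-202-3p rose 1.47-fold with metformin, from -3.45 ± 0.16 to -2.89 ± 0.06 (0.56, SE 0.11, adjusted p = 0.0465 by limma). In that reading miR-7050-5p, a late entry, rose 1.39-fold, from -3.88 ± 0.18 to -3.40 ± 0.05 (0.47, SE 0.10, adjusted p = 0.0465). All 3 metformin arrays lay above all 3 high fat diet arrays for both miRNAs. With all spots neither passed, at 0.64 (SE 0.15, adjusted p = 0.110) for miR-202-3p and 0.71 (SE 0.17, adjusted p = 0.110) for miR-7050-5p.

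The largest difference downward among named miRNAs was that of miR-451a, a marker of red blood cells. It stood 1.76-fold lower with all spots (-0.82, SE 0.31, adjusted p = 0.383) and 2.02-fold lower with the strips left out (-1.01, SE 0.29, adjusted p = 0.158), with no overlap of arrays and without passing. The diet-raised miR-34a-5p was at -0.21 (adjusted p = 0.723) and -0.56 (SE 0.14, adjusted p = 0.126), and miR-185-5p was at -0.27 in both readings. miR-122-5p was at 0.37 (adjusted p = 0.383) with all spots and 0.14 with the strips left out. Other differences that did not pass with all spots were those of miR-1904 (0.75), miR-3473g (0.61), miR-1949 (0.52), miR-149-3p (detected on 1 of 3 high fat diet arrays, so without a size), miR-5100 (0.42), let-7c-5p (0.38) and miR-107-3p (0.36). Without the strips miR-101c was at -0.43 and miR-27a-3p at -0.29. Late entries passed upward with the strips left out, with 1 of 19 tested risen (miR-7050-5p) and 0 fallen, also adjusted over the list alone. Of the 19 differences 10 were positive (median 0.10, adjusted p = 0.0489; adjusted p = 0.755 with an estimated correlation). This call ended without each of the control arrays (adjusted p = 0.106, 0.0573 and 0.0514), the second high fat diet array (0.303, with a median of -0.00) and the first or second metformin array (0.160 and 0.174). It also ended with quantile normalization (median 0.04, adjusted p = 0.314) and with the replicate block (0.0501), with a range over the alternatives of 0.00619 to 0.314. With all spots 0 lists passed with metformin, and 0 miRNAs passed among 139 tested by limma, with 15 at an unadjusted p under 0.05 (14 higher, 1 lower).

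With the strips left out 2 of 143 miRNAs passed by limma, both higher (13 at an unadjusted p under 0.05). The groups did not overlap for 29 (20.3%) there and for 31 (22.3%) with all spots. Chance gives 10% on average, with the same limit as above. The median difference was 0.16 with all spots and -0.06 with the strips left out. With all spots it was -0.00171 and -0.00419 without the first and the second control array, which are not in this contrast. The mostly upward differences with all spots thus depend on processing steps taken over all arrays. Of 137 miRNAs tested in both readings 63 changed sign. The count of 2 was 3 without the first or second control array, where miR-451a also passed, 1 without the third control array (miR-202-3p) or the third high fat diet array (miR-34a-5p), and 0 without the second high fat diet array or any 1 of the 3 metformin arrays. The calls ended with the row as a block (miR-202-3p 0.52, adjusted p = 0.369, range over the alternatives 0.0122 to 0.369; miR-7050-5p 0.42, adjusted p = 0.420, range 0.0210 to 0.420) and with the trend and robust options (0.0653 and 0.0669). The replicate block ended both calls as well, and that of miR-7050-5p also ended with quantile normalization (0.0740).

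The miRNAs called with the high fat diet were followed into the metformin group to see how far they lay from chow. With all spots 9 of 9 moved back toward or past the control level with metformin, and 0 were called back by limma (15 of all 139 at an unadjusted p under 0.05). Without the strips 19 of 20 moved back, the exception being miR-677-3p, and 1 was called in the opposite direction: miR-202-3p, which fell with the diet and rose with metformin. The count of such miRNAs was 0 with all spots, and in both readings 0 were called in the same direction. In simulated unchanged groups that share the high fat diet arrays, 9 (1 to 9) of the 9 most changed and 19 (2 to 20) of the 20 most changed miRNAs moved back, so such counts arise without an effect of metformin. The share of miRNAs with opposite signs in these contrasts was 73.4% in both readings, against 69.1% (30.2% to 91.4%) and 69.2% (30.1% to 90.9%) in the simulations. The correlation across miRNAs was -0.64 with all spots and -0.58 with the strips left out. The simulations gave -0.57 (-0.96 to 0.62) and -0.56 (-0.95 to 0.56), so these values lie inside the range that sharing alone gives. The count of 1 was 0 with the row block and the trend and robust options (10 and 17 miRNAs at an unadjusted p under 0.05 with metformin by limma). It was also 0 with the replicate block, and without the second high fat diet array or any 1 of the 3 metformin arrays. Without the third high fat diet array the miRNA called was miR-34a-5p in place of miR-202-3p.

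The metformin group was also set against the control group, which asks how far livers given the diet and the drug differed from livers on chow. In the strip-free reading miR-34a-5p rose 1.75-fold, from -1.92 ± 0.09 to -1.12 ± 0.04 (0.80, SE 0.14, adjusted p = 0.0143 by limma). In that reading miR-677-3p fell 1.54-fold, from -3.45 ± 0.05 to -4.08 ± 0.05 (-0.63, SE 0.09, adjusted p = 0.00534). All 3 metformin arrays lay on 1 side of all 3 control arrays for both. With all spots miR-34a-5p was at 0.63 (SE 0.20, adjusted p = 0.203) and did not pass.

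Other miRNAs with small p did not pass. Hypoxia-induced miR-210-3p was higher with all spots (adjusted p = 0.203), where it was detected on 1 of 3 control arrays, and at 0.72 (adjusted p = 0.0936) with the strips left out, detected on 2 of 3. miR-451a was at -0.93 (adjusted p = 0.203) and -0.90 (adjusted p = 0.150). With all spots miR-8110 was at -0.66, miR-3963 at -0.55, miR-3960 at -0.55, miR-574-5p at -0.53, miR-7042-5p at -0.52, miR-3102-5p at -0.49 and miR-342-3p at 0.46. Without the strips miR-211-3p was at -0.57, miR-6538 at -0.45, miR-425-5p at 0.34 and miR-202-3p at -0.13. Late entries passed downward in both readings with 0 of 19 called. Adjusted over the list alone 0 rose and 0 fell with all spots, and 0 and 1 with the strips left out. They were negative for 15 with all spots (median -0.29, adjusted p = 0.00872; adjusted p = 0.510 with an estimated correlation) and for 18 with the strips left out (median -0.29, adjusted p = 0.00181; adjusted p = 0.739 with an estimated correlation). Both calls ended without the first control array (adjusted p = 0.455 and 0.106, ranges over the alternatives 0.000876 to 0.455 and 0.000101 to 0.106). The call with all spots also ended with normexp (0.105), the total gene signal (0.197), the deposited value table (0.443) and only miRNAs detected on all arrays (0.136), and with no filter the list passed in the opposite direction (median 0, adjusted p = 0.0404). With the percentile over all probes the median turned to 0.36, below the 0.66 of all tested miRNAs there, and the list passed in the same direction relative to the others (adjusted p = 0.00876).

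Insulin and glucose regulators passed upward in both readings with 0 of 11 called, also adjusted over the list alone. All 11 were positive with all spots (median 0.22, adjusted p = 0.0165; adjusted p = 0.510 with an estimated correlation), with miR-107-3p at 0.36, miR-497a-5p at 0.32, miR-103-3p at 0.29 and miR-29c-3p at 0.24. Without the strips 10 were positive (median 0.12, adjusted p = 0.0391; adjusted p = 0.739 with an estimated correlation). Both calls ended with the row as a block (adjusted p = 0.0548 and 0.151, ranges over the alternatives 0.00665 to 0.882 and 0.0151 to 0.151). With all spots the call ended with the percentile over all probes (0.0595), the total gene signal (0.391), the deposited value table (0.882) and no filter (0.0704, with the test direction turned), and in the strip-free reading with quantile normalization (0.0776). With all spots it also ended without the first control array (0.235) and the second metformin array (0.0501), and in the strip-free reading without the first or the third control array (0.0908 and 0.0514) and the first metformin array (0.0998). The miRNAs reported raised in fatty livers passed upward with all spots. Of 17 on the array 5 were tested, 0 were called, also adjusted over the list alone, and all 5 were positive (median 0.36, adjusted p = 0.0133; adjusted p = 0.510 with an estimated correlation). The list shares miR-103-3p and miR-107-3p with the insulin and glucose regulators. It also shares miR-34a-5p with the lipid and cholesterol regulators and the p53-responsive list, and miR-199a-5p with the stellate markers. The results of the lists are therefore not independent of that list. Its members included miR-34a-5p at 0.63 and miR-107-3p at 0.36, and miR-199a-5p, which was detected on 0 of 3 control arrays. This call ended with the percentile over all probes (adjusted p = 0.0595), the total gene signal (0.151), the deposited value table (0.428) and no filter (0.388, with a median of 0 and the test direction turned). It ended as well without the first control array (0.111) and the second metformin array (0.0501; range over the alternatives 0.00665 to 0.428), and in the strip-free reading the list did not pass (median 0.09).

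With all spots 0 of 139 miRNAs passed by limma (15 at an unadjusted p under 0.05), and with the strips left out 2 of 143 passed (30 at an unadjusted p under 0.05). Groups did not overlap for 30 (21.6%) and 37 (25.9%), where chance gives 10% on average, with the same limit as above. With all spots the count was 2 without the first control array, miR-188-5p (-0.98) and miR-451a (-1.35), and 0 without any 1 of the others; miR-188-5p was named after its values were seen. With the strips left out the count was 3 without the first control array, 8 without the third and 1 without any 1 metformin array, where miR-34a-5p was lost. With the row as a block in that reading miR-34a-5p stood at 0.74 (adjusted p = 0.0548, range over the alternatives 0.00134 to 0.0985). Deviations of control and metformin arrays of the same replicate number correlated at 0.406, 0.200 and 0.209 with all spots. With the strips left out these were 0.362, -0.236 and 0.433. With the replicate numbers as a block 0 miRNAs passed with all spots by limma.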

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

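The tests of the cause of the strips were chosen after the result was seen. The share of spots of bright probes without signal stood out on 6 arrays, in spots that the comparisons do not look at singly. It was 38.6%, 34.2% and 25.5% on the control arrays in order of replicate number, 50.1% and 25.3% on the first and the third high fat diet arrays and 23.6% on the second metformin array. On the second high fat diet array it was 0 of 1310 spots, which allows a share of up to 0.229%. On the first and the third metformin arrays it was 0 of 1235 and 0 of 1190, which allow up to 0.243% and 0.252%. These limits cover counting error only. The header's median variation between spots of a probe was 52.0% to 283% on the 6 arrays and 6.19% to 7.39% on the other 3.

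These strips at the array edges are the first pattern weighed. The share of strip spots with signal was 0.743 of that in the same columns on arrays without strips (0.577 to 0.840 over 10 strips). That share takes in inner columns that read normally, so alone it cannot exclude an area without hybridisation. Such an area is argued against by the outermost columns, where signal matched arrays without strips 2 rows away (median correlation 0.866, 0.594 to 0.949). A displacement by 2 rows over the full width left out is argued against as well. In the innermost columns the match to arrays without strips was poor 2 rows away (correlation 0.180, 0.0841 to 0.236). It was close in the same row (0.867, 0.842 to 0.902). The rule for leaving out columns takes in steps where only 10% of the spots of bright probes lacked signal. The innermost columns can thus read mostly in their own row by that rule, so a displacement confined to outer columns stays open. A reading grid rotated against the spots may be the source: in 10 of 10 strips the match 2 rows away against that in the same row was better in the outermost columns (median correlation 0.866 against 0.172) than in the innermost. That contrast follows in part from the same rule, so it does not tell a rotation from a displacement of outer columns alone. No biological explanation was tested, because the design gives none for the position of a spot.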

How the results depend on the processing

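The reading with edge strips left out and the alternatives within it were chosen after the result was seen; the other alternatives were fixed beforehand. The count of miRNAs that passed with the high fat diet against control, 9 with all spots, was within 1.5 times of that with the mean over a miRNA's probes (10, of which 5 shared), only miRNAs detected on all arrays (12, 6 shared), the replicate block (7) and the trend and robust options (13, 9 shared). It was 2 with quantile normalization (miR-34a-5p and miR-3102-5p) and 1 with the percentile over all probes (let-7f-5p, named after its values were seen). Limma called 0 with normexp, the software's total gene signal, the deposited value table, no filter, the slide block, the slide row block and only the 2 groups of the contrast, with 58, 24, 14, 32, 32, 13 and 24 at an unadjusted p under 0.05. Leaving out each array gave 0 to 3. The count was 20 with the strips left out, 23 with quantile normalization as well, 22 with the replicate block, 0 with the slide row block (31 at an unadjusted p under 0.05), 18 with the trend and robust options, and 6 to 40 leaving out each array: 6 without the first high fat diet array, 40 without the third control array and 16 without either the third high fat diet or the first metformin array. In the fixed alternatives miR-34a-5p kept its sign (0.33 to 1.30, past the threshold in 5 of 22), as did miR-3102-5p (-1.13 to -0.45, in 7) and miR-202-3p (-0.63 to -0.12, in 3). In the 14 added ones these were past it in 13 each. The cause of these differences was not tested, except that leaving out arrays, the slide and row blocks (without the third control array) and fitting a pair of groups use fewer arrays.

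The count for metformin against high fat diet, 0 with all spots, was 1 with the percentile over all probes (let-7f-5p), 4 with the mean over a miRNA's probes (miR-1904, miR-202-3p, miR-6965-5p and miR-7050-5p), and 1 with the total gene signal and with the deposited value table (miR-702-3p in both). It was 2 with the strips left out, 2 with quantile normalization as well (let-7i-5p and miR-202-3p), 0 with the replicate block, the slide row block and the trend and robust options (limma, with 13, 10 and 17 at an unadjusted p under 0.05), and 0 to 3 leaving out each array in that reading. With all spots it was 0 without each array by limma. The count for metformin against control, 0 with all spots, was 1 with the total gene signal and with the deposited value table (miR-702-3p), and 0 to 2 leaving out each array. Without the strips it was 2, and there 1 with quantile normalization (miR-677-3p), 3 with the replicate block, 5 with the slide row block (miR-1187, miR-3082-5p, miR-466i-5p, miR-574-5p and miR-677-3p), 2 with the trend and robust options, and 1 to 8 leaving out each array. Members outside the naming rule were named after their values were seen. The count of miRNAs changed in opposite directions, 0 with all spots, was 1 with the percentile over all probes, 4 with the mean over a miRNA's probes, 1 with the strips left out, 2 with quantile normalization as well, 0 with the replicate block, the slide row block and the trend and robust options in that reading, 0 leaving out each array with all spots and 0 to 1 with the strips left out. The correlation of the contrasts stayed negative throughout, and leaving out each array with all spots gave -0.77 to -0.52.

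The number of lists and contrasts that passed, 5 of 36 with all spots, was 9 with normexp, 2 with the percentile over all probes, the total gene signal and the deposited value table, 3 of 30 with only miRNAs detected on all arrays, 32 of 63 with no filter, 3 with the slide row block, and 1 to 7 leaving out each array. In the strip-free reading it was 6, and there 2 with quantile normalization, 3 with the slide row block and 1 to 8 leaving out each array. With no filter most members lie at the floor. There 21 list tests that passed with or without the filter turned direction, 19 of them past the threshold with no filter, and 11 of their medians became 0, those of lipid and cholesterol regulators and of late entries in each contrast, of stellate markers in both high fat diet contrasts, of fatty liver miRNAs against control in both groups, and of insulin and glucose regulators with the diet. The other 10 had medians with the high fat diet of 0.0165 (miR-30), 0.21 (miR-29) and -0.0210 (miR-17-92), with metformin against high fat diet of 0.00350 (hepatocyte-enriched) and 0.0235 (miR-29), and with metformin against control of 0.11 (insulin and glucose), -0.0362 (let-7), 0.23 (miR-30), 0.0171 (miR-17-92) and 0.0118 (stellate). With the diet miR-1839-5p turned from -0.09 (detected on 1 of 3 control arrays) to 0.39 with the strips left out, 0.41 with quantile normalization as well, and 0.46 and 0.49 without the third control and the third high fat diet arrays. miR-7042-5p turned to 0.0917 with the strips left out and without the first control array.

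The median of all miRNAs moved with the processing. Normexp also uses median spot intensity, and the strip-free reading also changes how spots are averaged and marked, the probes kept and the floor, so these moves cannot be put down to 1 choice. With the high fat diet it was -0.22, with 26.6% of 139 higher, against 0.00 (48.2%) with quantile normalization, -0.33 (5.76%) with normexp, 0.24 (77.0%) with the percentile over all probes and 0.03 (54.5% of 143) with the strips left out. With all spots it was -0.04 (45.0%) without the second control array and -0.05 (43.1%) without the first high fat diet array. Without any other single array it was -0.22 to -0.13. With metformin against high fat diet it was 0.16 (81.3%), against 0.35 (95.7%) with the percentile over all probes, -0.03 (46.0%) with quantile normalization and -0.06 (37.1%) with the strips left out. With all spots it was -0.00171 (48.9%) and -0.00419 (48.6%) without the first and the second control array, which are not in this contrast. Without any other single array it was 0.07 to 0.21. With metformin against control it was 0.02 (53.2%), against 0.66 (97.8%) and -0.24 (19.4%) with the percentile over all probes and normexp. Of the calls with the diet 1 of 9 was higher, against 1 of 2 with quantile normalization, 0 of 1 with the percentile over all probes and 6 of 20 with the strips left out. For single miRNAs 2878 values stayed on the same side of the test under fixed alternatives, 162 were weaker, 17 stronger and 324 moved. Under added ones these were 1403, 48, 133 and 595. For lists they were 629, 25, 23 and 88, and 312, 33, 26 and 133. A change of sign of a value that had not passed is counted here as moved. Signal over background limits what can be seen: of 1881 miRNAs 139 lay far enough above it to be tested, and 0 to 11 of these lay at the floor on an array.

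Regrouping 3 against 3 arrays gives 10 splits, so no share under 0.1 can be reached. With all spots the real split gave 9 calls with the diet and the highest other 0 (1 of 10 splits as large), while both metformin contrasts gave 0 and 0 (10 of 10). Without the strips the real values were 20, 2 and 2 and the highest other 0 in each (1 of 10). If control arrays are taken as paired by replicate number with those of another group, 4 of the 10 splits part every pair. The 3 others of these gave 0 calls by limma. No such pairing is given in the sources used here. Deviations of high fat diet and metformin arrays of the same number correlated at 0.150, -0.149 and -0.109 with all spots. The best match had the own number in 12 of 18 cases with all spots. It did so in 6 of 18 with the strips left out. In that reading the replicate block ended the metformin calls against high fat diet of miR-202-3p and miR-7050-5p (adjusted p = 0.0696 each) and of late entries (0.0501; ranges over the alternatives 0.0122 to 0.369, 0.0210 to 0.420 and 0.00619 to 0.314).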

Other observations

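All tests of explanations in this part were chosen after the result was seen; the lists were fixed before the data were examined. The families and cell type markers that the comparisons leave out did not pass the list test with the high fat diet, and none of these lists passed in the metformin contrasts in either reading. Values are given with all spots first and with the strips left out second. Hepatocyte-enriched miRNAs (6 tested) had medians of -0.16 and 0.15 (adjusted p = 0.895 and 0.399 by camera in limma), with miR-148a-3p at 0.09 and 0.37. The let-7 family, which restrains proliferation, had medians of -0.15 (8 tested, adjusted p = 0.948) and 0.07 (9 tested, adjusted p = 0.704). The miR-30 family (5 tested) had 0.02 and 0.06 (adjusted p = 0.396 and 0.704), and the miR-29 family (3 tested), which represses collagen genes, had 0.21 and 0.22 (adjusted p = 0.267 and 0.235). The miR-17-92 clusters (8 tested) had -0.15 and 0.02 (adjusted p = 0.895 and 0.862), with a test direction opposite to the median in both. The p53-responsive list (3 tested) had -0.09 and 0.22 (adjusted p = 0.308 and 0.110); its members were miR-34a-5p, which rose, and miR-192-5p and miR-194-5p at 0.08 and 0.22 with the strips left out. Over the alternatives fixed beforehand the median of each of these lists took both signs.

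Markers of other cells were mostly below detection. Leukocyte markers (5 tested) had medians of -0.32 and 0.09 (adjusted p = 0.895 and 0.704), which also took both signs over the alternatives, with miR-342-3p risen in the strip-free reading and with miR-146a-5p at -0.57 and 0.15 and miR-142a-3p at -0.32 (detected on 1 of 3 control arrays) and -0.13. Lists with under 3 tested members were not tested. Of erythroid markers miR-451a alone was tested. Endothelial miR-126a-3p was at -0.42 and 0.18 and miR-322-5p at 0.14 and 0.39 with the diet. Epithelial miR-31-5p was at -0.17 and 0.30, miR-494-3p of the Dlk1-Dio3 cluster at -0.37 and -0.42, and miR-466i-5p of the Sfmbt2 cluster at -0.34 and -0.32, with miR-467f detected on 1 of 3 control and 1 of 3 high fat diet arrays in the latter reading. Of muscle, pancreas and neural markers and of the cluster of miR-183, miR-96 and miR-182, 0 could be tested with all spots, and with the strips left out neural miR-7a-5p was at -0.08. These single members were named after their values were seen.

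The lower level of late miRBase entries with the high fat diet, as the mean of the list minus the mean of the other tested miRNAs on each array, is the second pattern weighed. If the edge strips were the whole source, this measure would lie near 0 with the strips left out. There it was -0.363 (SE 0.151), with all 3 high fat diet arrays below all 3 controls. With all spots it was -0.299 (SE 0.180). The strip-free value lay past the bound set, but the list had already passed in that reading, so this was not an independent test. Its error is uncertain with 3 arrays a group, where the controls ran from 0.0610 to 0.504. The part of the strips was therefore not settled. A factor common to all miRNAs of an array cancels in this measure, so scaling was not tested, and without scaling the level of the list itself differed by 0.0262 (SE 0.158), so that the sign of its own change depends on the scaling. A single control library cannot be told apart from the diet, since without the first, the second and the third control array the measure was -0.225 (SE 0.0658), -0.417 (SE 0.229) and -0.446 (SE 0.202), and the second of these errors is too wide for the bound set. A change with the diet itself remains untested beside these.

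Opposite changes with the diet and with metformin across miRNAs are the third pattern weighed. With all spots the covariance of the contrasts was -0.0692, inside the range of simulated unchanged groups that share the high fat diet arrays (-0.194 to 0.0374), and with the strips left out it was -0.0343, inside -0.0436 to 0.00693. Sharing the high fat diet arrays may therefore account for the pattern without an effect of metformin. A reversal by metformin of the changes with the diet stays open and was not shown here.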
